A study of Homo sapiens with 8 samples.

How the data were processed

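Poly(A)-selected RNA of HCCLM3, an established and highly metastatic human hepatocellular carcinoma cell line, was sequenced in 8 libraries with paired-end reads. Per the labels, 4 libraries named NC have the genotype wild type, and 4 libraries named siRNA come from cells in which the circular RNA circPTK2 was silenced by a transiently transfected siRNA. The labels do not expand NC, and they do not say whether the NC cells received a control siRNA. Nor do they say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

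The deposited table holds 1 value per gene symbol and library, for 11818 genes. Its column names call the values counts, but no column holds whole numbers. The deposited values are a scaled read signal, in which the authors had divided the reads of each gene by a scaled library size. Column totals ran from 912904 to 1082965. Within each column every value was a whole multiple of 1 step, the value of 1 read, so reads could be recovered: 100% of the values came out whole within 0.02 reads. In 4 columns the smallest value was 2 steps, which was taken as 2 reads. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, HTSeq 0.12.4, DESeq2, edgeR and the genome build hg38 were involved; their roles and settings are not given in the sources used here, and neither is the use of strand in counting. Every gene in the file was above 1 in at least 3 libraries and the lowest mean over the 8 libraries was 0.725, so genes with low values had been removed before deposit. Reads from genes with overlapping or near-identical copies cannot be told apart at this level.

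Recovered reads on the listed genes came to 38728098, 40249129, 43512175 and 37087203 in NC replicates 1 to 4, and to 28659401, 31148074, 32532669 and 28077305 in siRNA replicates 1 to 4. A gene with no reads in a library is below 3 reads there, a floor that covers counting error only. Pairs of libraries all differed by more than sampling noise, so none was counted as a repeat of another.

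Because the values are normalized, the test stated before the data were examined for that case was used: limma 3.58.1 (trend and robust options, R 4.3.3) on log2(value + 1), for the 11812 genes with a value of at least 1 in at least 4 libraries, with the group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The remaining 6 genes were not tested. Log2 changes are therefore on the log2(value + 1) scale, which understates the change of low genes, and fold values in the text are ratios of group means on the scale of the table. Means are given with the SD over 4 libraries.

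Replicate numbers are shared by the groups, but the labels tie them to no common day or passage, so the fit had no replicate block. Data were also simulated from the recovered reads for this comparison, with 11734 genes tested. The procedure called 96.3% of 54 genes changed 4-fold, 49.2% of 65 genes changed 2-fold and 11.4% of 79 genes changed 1.5-fold. There were 10 false calls. The simulated NC libraries had no split into pairs and few genes were changed, so these figures may not hold for the real libraries.

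The 27 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01) on the same values, adjusted over the lists. An estimated correlation, the rotation test fry and a rank form of camera were alternatives, each run on all 8 libraries only. The genes to be named were also fixed by rule: PTK2, the 12 largest increases and the 12 largest decreases among genes past the threshold with a mean value of at least 5, no overlap between the groups and no clone or LOC name, up to 4 members with the smallest p of each described list, and the 3 genes with the largest share of the values. The rule for increases and decreases left 4146 genes to choose from. The values of 1 list member that the rule takes are not reported here.

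Alternatives planned at that stage were DESeq2 1.42.0, limma-voom, edgeR with DESeq2 size factors, library totals alone, pseudocounts of 0.1 and 5, other filters, adjusted p under 0.01, a minimum change of 1.2-fold, a replicate block and leaving out each library. Count tests ran on the recovered reads, since the table was not one of counts. Alternatives added after seeing the data were edgeR 4.0.16 on the recovered reads, which called 5001 genes, leaving out NC replicates 1 and 2 or NC replicates 3 and 4, removing a trend with GC content and transcript length from every library, and removing 10 Mb bin medians from every library.

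Gene positions, GC content, lengths and 3' UTR sequences came from GENCODE v29 on GRCh38, matched by gene symbol; 11806 of the 11818 symbols had a position and 12 did not. For the position test, 10127 genes with a mean value of at least 5 were placed in 279 bins of 10 Mb with at least 10 genes each, and the variance of the bin medians was compared with that from 1000 shuffles of the genes. GC content and length were available for 11800 tested genes (99.9%). For the siRNA seed test, 15872 words of 7 bases were tested in the 3' UTRs of 11650 genes, with UTR length, GC content and expression level in the model. The circular RNA itself was not analysed here: it carries no poly(A) tail, and a table by gene does not separate it from the linear transcripts of its host gene.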

Results

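The study asked which downstream signals change when circPTK2, a circular RNA made from exons of the PTK2 gene, is silenced in HCCLM3 hepatocellular carcinoma cells. Messenger RNA was profiled in 4 NC libraries, labelled wild type, and 4 libraries from cells transfected with an siRNA against circPTK2. Recovered reads on the listed genes ranged from 37087203 to 43512175 in the NC libraries and from 28077305 to 32532669 in the siRNA libraries. The mitochondrial transcript MT-CO1, the receptor tyrosine kinase gene MET and the ferritin light chain gene FTL took the largest shares, together 2.30% to 4.08% of the values of a library.

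The siRNA libraries lay close together, whereas the NC libraries formed 2 pairs. Spearman correlations across genes ran from 0.990 to 0.995 among the siRNA libraries and from 0.985 to 0.987 within the NC pairs, replicates 1 with 2 and 3 with 4. Between the NC pairs they were 0.919 to 0.938, close to the 0.894 to 0.933 between NC and siRNA libraries. Principal component 1 held 71.8% of the variance of the 500 most variable genes and separated the groups, and component 2, with 18.9%, separated the NC pairs. The mitochondrial share of reads followed the same split, at 5.32% and 5.01% in NC replicates 1 and 2, 1.96% and 2.19% in NC replicates 3 and 4, and 4.39% to 5.59% in the siRNA libraries.

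**Figure D1:**
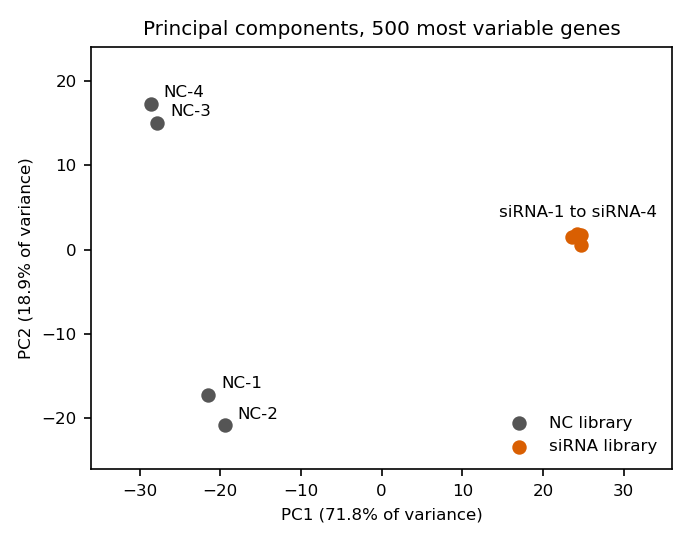
Principal components 1 and 2 of log2(value + 1) for the 500 most variable genes, with each point a library, grey for NC and orange for siRNA. The siRNA libraries sit together on the right of component 1 (71.8% of the variance), and NC-1 and NC-2 lie apart from NC-3 and NC-4 on component 2 (18.9%).

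PTK2, which encodes focal adhesion kinase, was the host gene to examine first. It lies on chromosome 8 from 140657900 to 141002216 on the minus strand (GRCh38). Its mRNA stood at 178, 227, 175 and 161 in NC replicates 1 to 4 and at 210, 217, 219 and 204 in siRNA replicates 1 to 4. The means were 185 ± 28.8 (SD, n = 4) and 213 ± 6.89 (SD, n = 4), a log2 change of 0.21 with an SE of 0.11 that did not pass the limma test (adjusted p = 0.167). Without NC replicate 2 the log2 change was 0.31 (limma adjusted p = 0.0153), and without NC replicates 1 and 2 it was 0.34 (limma adjusted p = 0.00166). It was 0.15 without NC replicate 4 (limma adjusted p = 0.337) and 0.079 without NC replicates 3 and 4 (limma adjusted p = 0.51). These values describe the linear mRNA and do not measure the circular RNA or its knockdown.

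A large part of the transcriptome differed between the groups. Of 11812 genes tested, 5015 (42.5%) passed the limma threshold, 2558 higher and 2457 lower in the siRNA libraries. An absolute log2 change of at least 1 was seen for 1444 of them, 750 higher and 694 lower. The values of the groups did not overlap for 5111 genes (43.3%). Chance gives 2.86% for 4 libraries against 4, but only where the libraries are independent. The NC libraries formed pairs and separate cultures are not stated, so that share is no measure of chance here. The count rose to 7782 without NC replicates 1 and 2. Between the fits without NC replicates 1 and 2 and without NC replicates 3 and 4, 4399 genes were called in the same direction and 700 in opposite directions. Of the 4399, 4361 were also called with all 8 libraries. For all 5015 calls the siRNA mean lay on the same side of both NC pair means. The test nearly fixes this outcome. A gene with its siRNA mean between the pair means has an NC spread too large against the difference to pass easily. It is therefore no evidence of agreement between the NC pairs.

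FLNC, the actin cross-linking protein filamin C, had the largest increase by log2 change, from 4.28 ± 2.03 to 487 ± 52.9 (SD, n = 4 each), a log2 change of 6.60 with an SE of 0.25 (limma adjusted p = 1.07e-06). It lies on chromosome 7 from 128830377 to 128859274. The urea transporter gene SLC14A1 rose from 0.671 ± 0.366 to 84.2 ± 20.1, and the tetraspanin gene TSPAN8 from 0.247 ± 0.189 to 54.2 ± 4.70. ABCB1, the drug efflux pump P-glycoprotein, rose 72.8-fold, from 1.14 ± 0.224 to 83.2 ± 5.39. The branched-chain aminotransferase gene BCAT1 rose 53.6-fold and PHGDH, the first enzyme of serine synthesis, 27.5-fold. The cancer-testis gene SSX1 rose 54.2-fold and the collagen VI gene COL6A3 34.5-fold. SLAMF7, a receptor known from immune cells, rose from 0.205 ± 0.19 to 29.02 ± 4.94, and the retinol carrier RBP4 from 0.189 ± 0.152 to 23.4 ± 3.67. CDCA7L, on chromosome 7 from 21900900 to 21946084, had no reads in any NC library and a mean of 18.7 ± 1.44 in the siRNA libraries, at least 251-fold higher with a floor of 3 reads per library. EGFLAM, a matrix protein gene, rose from 0.0624 ± 0.0931 to 15.9 ± 1.09. The limma adjusted p of these 12 genes ranged from 1.21e-07 to 0.000126.

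Among the decreases, ITM2A, a membrane protein gene on chromosome X from 79360384 to 79367667, fell from 58.1 ± 14.9 to 0.201 ± 0.264, a log2 change of -5.61 with an SE of 0.22 (limma adjusted p = 1.34e-06). The cancer-testis genes MAGEA12 and CSAG1, neighbours on the X chromosome with near-identical family copies that leave their values uncertain, fell from 30.5 ± 2.18 to 0.235 ± 0.2 and from 16.7 ± 2.13 to 0.098 ± 0.196. The fibrinogen chain genes FGA and FGB, neighbours on chromosome 4 and products of hepatocytes, fell from 29.9 ± 12.1 to 1.06 ± 0.536 and from 23.7 ± 12.3 to 0.578 ± 0.07. CPLX2, a regulator of vesicle fusion, fell 33.0-fold, the secreted olfactomedin OLFM1 19.1-fold, and the anion transporter gene SLC26A9 39.9-fold. ACKR3, an atypical receptor for the chemokine CXCL12, fell 12.9-fold and NHSL2 57.8-fold. MAP2K6, a kinase upstream of p38, fell from 52.4 ± 6.24 to 5.14 ± 2.14. UGT1A9, a glucuronidation enzyme that shares exons with its gene family and is therefore uncertain, fell 14.7-fold. The limma adjusted p of these 12 genes ranged from 3.89e-07 to 0.00107.

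**Figure D2:**
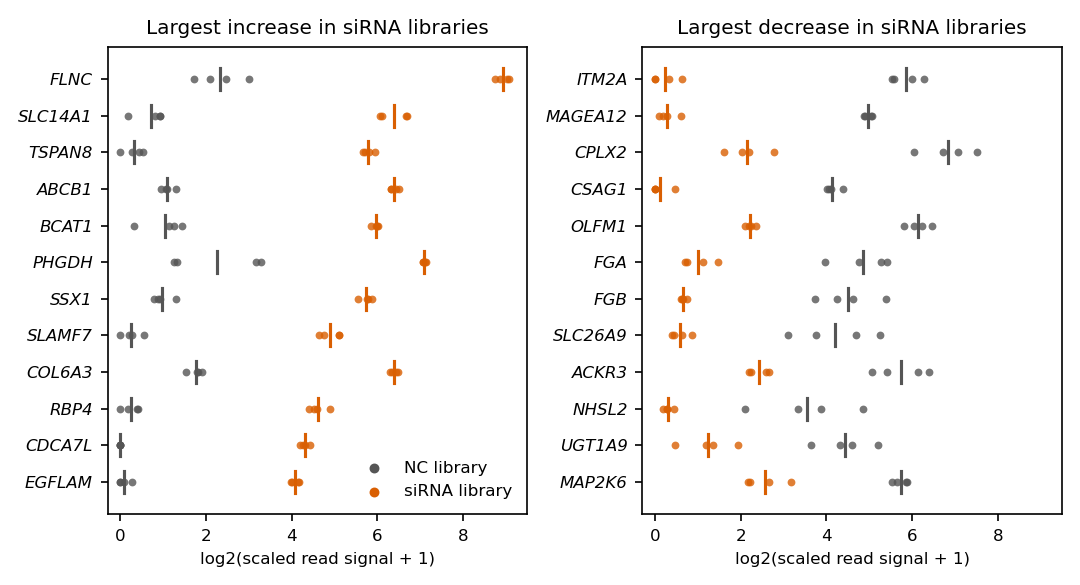
Values of the 12 genes with the largest increase (left) and the 12 with the largest decrease (right), as log2(scaled read signal + 1) on the horizontal axis, with a point per library, a bar at the mean of 4, grey for NC and orange for siRNA. The groups do not overlap for any of the 24 genes, as the rule that chose them required, and CDCA7L is at 0 in every NC library.

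Some of these genes were near absent in one group. TSPAN8, SPOCK1, SLC14A1, SLAMF7, RBP4, EGFLAM, CNTN6 and CDCA7L were under 1 in every NC library and at 10 or more in every siRNA library. Conversely, 4 genes, MAGEA12, ITM2A, FGB and CSAG1, were under 1 in every siRNA library and at 10 or more in every NC library. Within the NC group, UNC5B, TMOD2, CHAC1 and ALOXE3 were under 1 in replicates 3 and 4 and at 10 or more in replicates 1 and 2, and 0 genes were the other way. Every gene in the file was above 1 in at least 3 libraries. A gene present in only 1 NC pair and in no siRNA library could therefore not appear. The counts within the NC group are thus not comparable with those between the groups. SPOCK1 and CNTN6 were named from the count between the groups, after their values were seen.

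Of the 27 gene lists, 2 passed the camera threshold, both lower in the siRNA libraries. Genes of G2/M and mitosis fell as a list (median log2 change -0.67, camera adjusted p = 0.000166, adjusted p = 0.962 with an estimated correlation): 15 of 28 measured members fell and none rose, or 16 and none adjusted over the list alone. The mitotic cyclin gene CCNB2 fell from 96.2 ± 14.4 to 41.1 ± 2.34, the kinesin gene KIF23 from 136 ± 27.4 to 50.3 ± 2.72, the spindle midzone gene PRC1 from 195 ± 29.3 to 83.1 ± 7.53, and the centromeric histone gene CENPA from 17.3 ± 3.06 to 6.63 ± 0.746. CCNB2, KIF23 and PRC1 lie on chromosome 15, and 8 of the 15 members that fell lie on chromosome 10 or 15, where most genes were lower in the siRNA libraries. The 20 members elsewhere had a median log2 change of -0.48, and with 10 Mb bin medians removed, an alternative chosen after seeing the data, the list's median was -0.55 (camera adjusted p = 0.000104). Without NC replicates 1 and 2 the list's median was -1.17 (camera adjusted p = 9.31e-10), and without NC replicates 3 and 4 it was -0.32 (camera adjusted p = 0.038).

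Genes of cholesterol synthesis and uptake also fell as a list (median log2 change -0.96, camera adjusted p = 0.000635, adjusted p = 0.962 with an estimated correlation). Of 25 measured members 9 fell and none rose, also when adjusted over the list alone. The farnesyl diphosphate synthase gene FDPS fell from 248 ± 101 to 60.3 ± 1.78, the reductase gene TM7SF2 from 8.47 ± 2.38 to 1.99 ± 1.01, and SREBF2, the transcription factor of the pathway, from 125 ± 6.58 to 89.4 ± 2.82. The decrease was set mostly by NC replicates 3 and 4. The list's median centred log2 level was 1.14 and 1.16 there, -0.29 and -0.31 in NC replicates 1 and 2, and -0.43 to -0.34 in the siRNA libraries. Without NC replicates 3 and 4 the median log2 change was -0.19 and the list no longer passed (camera adjusted p = 0.134). Without NC replicate 3 alone the median was -0.60 (camera adjusted p = 0.00762), and without NC replicates 1 and 2 it was -1.67 (camera adjusted p = 1.2e-10).

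**Figure D3:**
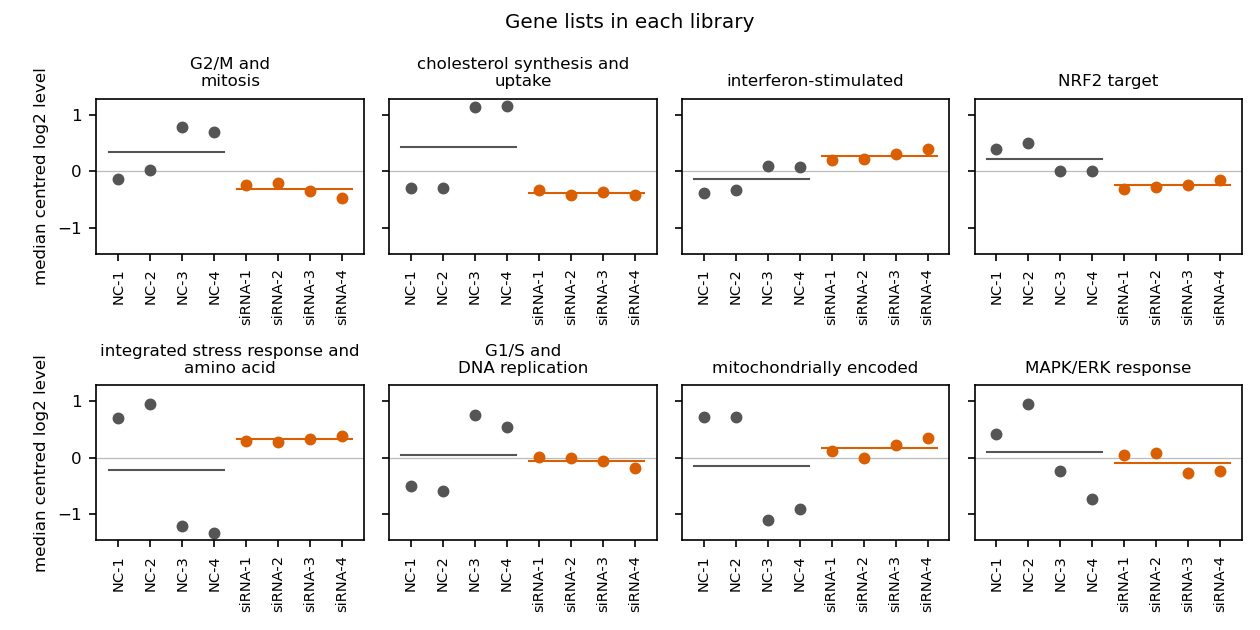
Median log2 level of the members of 8 gene lists in each library, each gene centred on its mean over the 8 libraries, with a point per library, lines at the group means, grey for NC and orange for siRNA. Cholesterol genes stood at 1.14 and 1.16 in NC-3 and NC-4 and below 0 in the other libraries, and the amino acid, replication and mitochondrial lists in the siRNA libraries lay between the NC pairs.

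For 3 lists the camera test passed in opposite directions depending on which 2 NC libraries were left out, and none of the 3 passed with all 8. These tests used the preset correlation of 0.01. Estimated over all 8 libraries, the correlations of the 3 lists were 0.949, 0.802 and 0.984, in the order given below. No estimated correlation was used for the fits without an NC pair, so significance there may be overstated. The integrated stress response and amino acid list had a median log2 change of 0.66 (camera adjusted p = 0.322), 1.56 without NC replicates 1 and 2 (adjusted p = 1.43e-10) and -0.49 without NC replicates 3 and 4 (adjusted p = 0.00511). Of its 25 measured members 3 rose and none fell, 2 and none adjusted over the list alone: PHGDH, the transcription factor gene ATF5 (85.8 ± 26.6 to 182 ± 10.7) and the lipoprotein receptor gene VLDLR, which did not pass without siRNA replicate 2 or 4 (limma adjusted p = 0.0514 and 0.0549). The asparagine synthetase gene ASNS had values of 531, 637, 39.6 and 39.4 in NC replicates 1 to 4 and of 781 to 844 in the siRNA libraries. It did not pass with all 8 libraries. ASNS passed without NC replicate 1 or 2 (limma adjusted p = 0.0288 and 0.0152). It also passed without both (log2 change 4.325, limma adjusted p = 3.06e-11) and without NC replicates 3 and 4 (0.48, limma adjusted p = 0.00104). The list was past the threshold without NC replicate 2 alone (median 1.13, camera adjusted p = 0.0287). The G1/S and DNA replication list had a median of -0.16 (adjusted p = 0.887), -0.68 without NC replicates 1 and 2 (adjusted p = 0.000131) and 0.47 without NC replicates 3 and 4 (adjusted p = 0.0013). Of its 26 members the cyclin gene CCND1 (229 ± 56.8 to 576 ± 48.1) and the phosphatase gene CDC25A rose, and CDC45 and RFC4 fell, with 2 higher and 1 lower adjusted over the list alone. RFC4 did not pass without NC replicate 3 or 4 or any 1 of the siRNA libraries (limma adjusted p = 0.0514 to 0.0847). The mitochondrially encoded list had a median of 0.37 (adjusted p = 0.665), 1.13 without NC replicates 1 and 2 (adjusted p = 8.14e-06) and -0.56 without NC replicates 3 and 4 (adjusted p = 0.0141). MT-CO1 was the only one of its 13 members to pass, with none adjusted over the list alone.

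None of the signalling lists passed the camera test with all 8 libraries. In the list of focal adhesion and integrin genes, 3 of 23 members rose and 5 fell (camera adjusted p = 0.787; the same counts adjusted over the list alone), with the parvin gene PARVA up 1.43-fold and LIMS1 up 1.73-fold, and the paxillin gene PXN down 1.85-fold. The MAPK/ERK response list had no increases and 2 decreases among 28 members (adjusted p = 0.665; the same over the list alone), SPRED1 and ETV4. It passed without NC replicates 3 and 4 (median -0.81, adjusted p = 0.000349), but its median was 0.33 without NC replicates 1 and 2 (adjusted p = 0.0924). Of 21 YAP/TAZ targets 6 rose and none fell (adjusted p = 0.322; the same over the list alone), among them IGFBP3 from 1.94 ± 0.621 to 18.1 ± 3.66 and CRIM1. Without NC replicates 1 and 2 that list passed (median 0.96, adjusted p = 0.00366), and without NC replicates 3 and 4 its median was -0.20 (adjusted p = 0.995). TGF-beta response genes had 5 increases and 4 decreases among 23 (adjusted p = 0.922; the same over the list alone), with TGFB2 up 2.47-fold and ID1 down 3.30-fold. Wnt/beta-catenin targets had 2 and 2 among 13 (adjusted p = 0.947; the same over the list alone), the inhibitor gene DKK1 up 2.15-fold and TBX3 down 4.66-fold.

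Inflammatory and stress lists did not pass either with all 8 libraries. Of 19 interferon-stimulated genes 7 rose and 1 fell (camera adjusted p = 0.17), 8 and 1 adjusted over the list alone, with ISG15 up from 11.8 ± 1.58 to 32.2 ± 1.47 and STAT2 down 1.91-fold. Without NC replicates 3 and 4 that list passed (median 0.63, adjusted p = 0.00237), and without NC replicates 1 and 2 it did not (median 0.11, adjusted p = 0.522). NF-kB and inflammatory genes had 6 increases and 1 decrease among 21 (adjusted p = 0.322; the same over the list alone), with BIRC3 up 3.57-fold and CXCL8 down 4.48-fold, and passed without NC replicates 1 and 2 (median 0.46, adjusted p = 0.0304) but not without NC replicates 3 and 4 (median 0.086, adjusted p = 0.995). NRF2 targets had 2 increases and 10 decreases among 23 (adjusted p = 0.114), 3 and 12 adjusted over the list alone. The aldo-keto reductase gene AKR1B10 fell 1.86-fold, a family in which near-identical copies leave values uncertain, and the glutathione reductase gene GSR fell 1.80-fold while FTL rose 1.58-fold. The NRF2 list passed with library totals alone (median -0.56, adjusted p = 0.0367), without NC replicate 3 (median -0.58, adjusted p = 0.0391), without NC replicate 4 (median -0.62, adjusted p = 0.0193) and without both (median -0.80, adjusted p = 0.00133), but not without NC replicates 1 and 2 (median -0.20, adjusted p = 0.428). Heat shock genes had 5 and 2 among 18 (adjusted p = 0.665; the same over the list alone), and passed without NC replicates 3 and 4 (median 0.50, adjusted p = 0.0013), while without NC replicates 1 and 2 the median was -0.33 (adjusted p = 0.428). ER chaperone genes had 4 increases and 5 decreases among 23 (adjusted p = 0.733; 2 and 4 over the list alone). Of 19 p53 targets only TIGAR passed (adjusted p = 0.895; none over the list alone), and not without NC replicates 1 or 4 or siRNA replicates 1, 2 or 3, each left out in turn (limma adjusted p = 0.0714 to 0.0955).

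Lists of cell identity moved in mixed directions. Of 21 mesenchymal and invasion genes 7 rose and 6 fell (camera adjusted p = 0.922; 8 and 7 adjusted over the list alone): the metalloprotease gene MMP7 rose from 47.4 ± 18.2 to 263 ± 35.7, while MMP14 fell from 95.3 ± 11.9 to 26.7 ± 2.71, S100A4 from 670 ± 99.0 to 223 ± 11.4 and the fibronectin gene FN1 from 7797 ± 541 to 4232 ± 226. Epithelial genes had 6 increases and 2 decreases among 19 (adjusted p = 0.665; 7 and 2 over the list alone), with the tight junction genes OCLN up 3.28-fold and CLDN1 up 3.85-fold. Hepatocyte genes had 6 and 7 among 18 (adjusted p = 0.787; 6 and 8 over the list alone). RBP4 and SERPINA1 rose while FGA and FGB fell. Of the markers of fibroblasts, endothelium and leukocytes 5 were measured (adjusted p = 0.665): KDR rose from 23.9 ± 5.23 to 113 ± 13.5 and CD163 from 0.157 ± 0.0566 to 2.27 ± 0.224, PECAM1 fell from 13.0 ± 5.11 to 3.96 ± 0.735, and 2 rose and 2 fell adjusted over the list alone. This list was the only one to pass fry for a common direction (fry adjusted p = 0.000464). The fry test takes a list by itself and does not compare it with other genes. Its mixed form, which counts changes in either direction, passed for most lists, for example hepatocyte genes (fry mixed adjusted p = 1.79e-09). The mixed form did not pass for the G1/S, p53, MAPK/ERK, integrated stress response and mitochondrially encoded lists.

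The remaining lists covered metabolism, organelles and RNA handling. Fatty acid and triglyceride genes had 4 increases and 9 decreases among 23 (camera adjusted p = 0.665; 4 and 10 adjusted over the list alone), with the desaturase gene FADS2 down from 402 ± 127 to 43.5 ± 10.1, and passed without NC replicates 1 and 2 (median -0.77, adjusted p = 0.0304) but not without NC replicates 3 and 4 (median 0.097, adjusted p = 0.981). Hypoxia and glycolysis genes had 4 and 6 among 24 (adjusted p = 0.787; 5 and 6 over the list alone), with the phosphofructokinase gene PFKP down from 448 ± 38 to 224 ± 9.31. Lysosome and autophagy genes had 9 and 5 among 28 (adjusted p = 0.665; the same over the list alone), with the protease genes CTSL down 3.76-fold and CTSD up 1.55-fold. Oxidative phosphorylation genes of the nucleus had 7 and 4 among 28 (adjusted p = 0.887; 5 and 2 over the list alone), ribosomal protein genes 7 and 6 among 36 (adjusted p = 0.665; the same over the list alone), and histone genes 1 and 1 among 8 (adjusted p = 0.665; 0 and 1 over the list alone). RNA silencing and circular RNA handling genes had 3 and 5 among 24 (adjusted p = 0.733; 2 and 5 over the list alone), with the microprocessor gene DGCR8 down 1.78-fold and the exportin gene XPO5 up 1.40-fold. The sign of the median and of the mean differed for the focal adhesion, p53, TGF-beta, Wnt, and hypoxia lists and for the RNA silencing list. With an estimated correlation the adjusted p was 0.962 for every list.

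The differences also followed position along the chromosomes. All 14 bins of 10 Mb on chromosome 10 and all 8 on chromosome 15 had a lower median in the siRNA libraries, with median log2 differences of -0.35 over 403 genes and -0.45 over 327 genes. On chromosome 15, 166 genes were called lower and 15 higher, and the median centred log2 level was 0.22 to 0.26 in each NC library and -0.24 to -0.20 in each siRNA library. Chromosome 3 went the other way, with 17 of 18 bins higher and a median of 0.32 over 581 genes. The variance of the bin medians was 3.672 times that with shuffled positions (permutation p = 0.001, the smallest that 1000 shuffles can give).

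**Figure D4:**
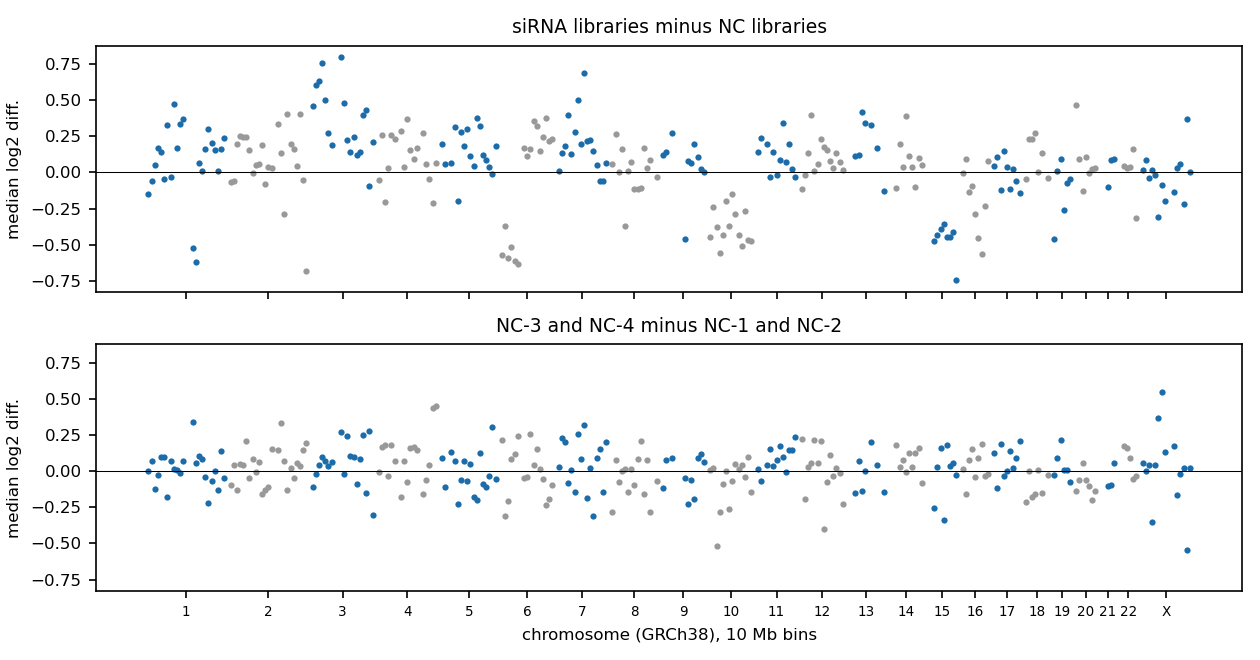
Median log2 difference of the genes in each 10 Mb bin along the chromosomes (GRCh38), siRNA minus NC libraries (top) and NC-3 and NC-4 minus NC-1 and NC-2 (bottom), with a point per bin and colours alternating between chromosomes. In the top panel all bins of chromosomes 10 and 15 lie below 0 and 17 of 18 bins of chromosome 3 lie above.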

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

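A library stood far from the other 3 of its group in 9 of 314 groups of 4 values examined, where chance flags about 1 in 20 groups, or 15.7 here. That rate assumes independent values. The NC libraries formed pairs, which makes an outlying NC library hard to flag, so fewer flags than 15.7 do not show an absence of outlying libraries. NC replicate 1 had 0.473 for PMEPA1, against 0 to 0.0807 in the other NC libraries. NC replicate 4 had 8335 for FTL, against 7178 to 7286. The median level of the hypoxia and glycolysis list was 0.136 in NC replicate 3 and 0.00903 to 0.0284 in the others, and that of the nuclear oxidative phosphorylation list was 0.098 in NC replicate 4 and -0.0736 to -0.0518 in the others. Among the siRNA libraries, replicate 1 had 0.392 for CSAG1, which was at 0 in the other 3, and 42.6 for COX5A, against 32.3 to 32.6. Replicate 2 had 179 for XPO5, against 163 to 165, replicate 3 had 7.74 for CENPA, against 6.15 to 6.40, and replicate 4 had 2.60 for CD163, against 2.13 to 2.21.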

How the results depend on the processing

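The added alternatives (edgeR on recovered reads, the left-out NC pairs, the GC and length correction and the bin correction) were chosen after seeing the data. Between 3853 and 5535 genes were called with any 1 library left out, 5690 with DESeq2 and 5001 with edgeR, of which 4987 and 4842 were shared with the 5015. At adjusted p under 0.01 the count was 3034 (1570 higher, 1464 lower), and against a minimum change of 1.2-fold 2675 (1367 higher, 1308 lower), since both ask for more. A pseudocount of 5 left 747 genes with a log2 change of at least 1, since it shrinks the change of low genes. Without NC replicates 1 and 2 there were 7782 calls (3953 higher, 3829 lower), 2307 of them with a log2 change of at least 1; without NC replicates 3 and 4 there were 6830. The cause was not tested, though the remaining NC libraries resemble each other more. The log2 change of PTK2 ranged from 0.1458 to 0.3106 with 1 library left out, was 0.3399 without NC replicates 1 and 2 and 0.0787 without NC replicates 3 and 4. Lists past the threshold were 0 to 1 up with 1 library left out, 4 up and 4 down without NC replicates 1 and 2, 3 up and 5 down without NC replicates 3 and 4, 1 up and 0 down with fry, and 0 down with an estimated correlation. Without NC replicates 3 and 4 the list medians turned to 0.469 for G1/S and DNA replication, -0.492 for the integrated stress response and -0.561 for mitochondrially encoded genes; the cause was not tested. With all tested genes component 1 held 61.52% of the variance. The mitochondrially encoded list has no value under the bin correction, which left out that genome. After each gene's group mean was subtracted, the deviations of same-numbered NC and siRNA libraries correlated at -0.0682, 0.146, -0.0656 and 0.161. These values gave no sign that the numbers pair the libraries, and not every library's deviations correlated best with its own number. With a replicate block 4546 genes were called, 4383 of them shared. Over the named genes and these alternatives, 3037 values kept their side of the threshold, 66 lost and 55 gained a call, and 0 reversed. These genes were mostly picked for non-overlapping groups or a small p, so leaving out libraries could reverse few of them. Genes near the floor are limited by depth.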

Other observations

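The tests of chance, position, GC content and siRNA seed were set before their results were seen; the chromosome stretches and the genes near ABCB1 were picked afterwards. Parts of chromosomes also moved as blocks. On chromosome 6 from 1 to 60000000, 295 genes had a median log2 difference of -0.55, with 163 called lower and 16 higher. On chromosome 1 from 140000001 to 160000000 the median was -0.60 over 168 genes, with 104 called lower and 6 higher. On chromosome 3, which was also higher as a whole, the median from 1 to 40000000 was 0.64 over 115 genes, with 72 called higher and 3 lower. In each stretch all 4 siRNA libraries lay on one side of all 4 NC libraries, for example -0.23 to -0.27 against 0.21 to 0.28 on chromosome 6.

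The 10 Mb bin on chromosome 7 that starts at 80000001 and holds ABCB1 had a median log2 difference of 0.689 over 10 genes, 6 with a higher and 4 with a lower value in the siRNA libraries, passing or not. The median was 0.853 against NC replicates 1 and 2 and 0.209 against NC replicates 3 and 4. ABCB4, a neighbour of ABCB1 and also a transporter gene, rose from 0.346 ± 0.0983 to 4.29 ± 0.218 (SD, n = 4, limma adjusted p = 1.63e-05). CROT fell from 5.33 ± 1.81 to 1.68 ± 0.74, and DBF4 was at 55.2 ± 17.4 and 48.4 ± 6.58 (limma adjusted p = 0.617). Further along, the neighbouring genes SGCE and PEG10, known to be imprinted, rose from 5.94 ± 1.42 to 60.6 ± 2.66 and from 59.2 ± 45.1 to 237 ± 108 (limma adjusted p = 4.52e-06 and 0.0161).

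Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many calls as the 5015 between the groups, the real one. The highest other gave 2. Every other split divides the closely alike siRNA libraries, so low counts there follow from that likeness. The splits treat the libraries as interchangeable and cannot exclude a grouping by culture or batch. Removing a trend with GC content and length left 99.4% as many calls, which argues against such a trend, and the 7-base word of 3' UTRs with the most negative t statistic had a shift of -0.082 (Bonferroni-adjusted p = 0.497). Against NC replicates 3 and 4 the same word had -0.113 (Bonferroni-adjusted p = 0.0152). For NC replicates 3 and 4 minus NC replicates 1 and 2, 3 words passed with a negative and 2 with a positive shift. The word with the most negative t statistic there had a shift of -0.098 (Bonferroni-adjusted p = 1.93e-05). Words can thus pass between NC libraries alone. In no comparison did a word with a Bonferroni-adjusted p under 0.05 reach the shift of -0.2 set beforehand. A seed effect that is weaker or on fewer genes stays open. A candidate explanation is that the groups were grown from HCCLM3 populations with different chromosome copy number, and the bounds set for it beforehand were met. Bin medians varied 3.672 times as much as with shuffled positions (permutation p = 0.001), against 1.297 times between the NC pairs (permutation p = 0.004). The ratios were 3.551 and 2.683 against NC replicates 1 and 2 and against NC replicates 3 and 4. Copy number itself was not measured, so the explanation stays open. After removing bin medians 4302 genes were called, against 4970 before among the same genes, with 3727 in both. The removal cannot take out copy number changes smaller than a bin, so it does not show how many calls dosage accounts for. An effect of silencing circPTK2 on these genes stays open, and no test here separates it from a difference between populations that follows the group.

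The NC libraries split into replicates 1 and 2 and replicates 3 and 4, with ASNS at 531 and 637 against 39.6 and 39.4, and CDC45 at 14.5 and 16.7 against 41.1 and 36.4. GC content and length explained 0.6% of the variance of this difference across genes, which argues against such a trend. Whether copy number also differed cannot be told apart from other causes. Bin medians varied 1.297 times as much as with shuffled positions (permutation p = 0.004), between the bounds set for either answer. A difference in culture state or nutrients was not tested, and the labels name no batch.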
